A study of Homo sapiens with 12 samples.

How the data were processed

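RNA sequencing of MDA-MB-231 cells was analysed in 4 groups of 3 libraries: DMSO, DAC (10 µM), DEX (1 µM) and DAC+DEX, all from day 6. Per the labels' protocols, cells were grown in DMEM with serum, RNA was isolated with TRIzol and column purification, and libraries were made with an mRNA library kit. The deposited table holds raw read counts per Ensembl gene for each library, with 58884 genes and 0 columns without a sample. That the values are raw counts was read from the values, which are whole numbers with unequal totals. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.38, the genome build was GRCh38, and CASAVA, FastQC, MultiQC and DESeq2 1.22.1 were used. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Coordinates, gene types and lengths were taken from GENCODE release 29, which holds 58611 of the gene IDs, and 58876 IDs had a symbol from it or from a table of gene names. Gene length is the summed length of the exons. Reads were not available here, so alignment was not checked.

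Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum of 10 counts), which left 18526, and libraries were scaled by TMM. The TMM factors ranged from 0.7304 to 1.18. All 12 libraries entered 1 quasi-likelihood fit with a mean per group and 8 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were DAC, DEX and DAC+DEX each against DMSO, DAC+DEX against DAC and against DEX, and the difference between the DEX effects with and without DAC (the interaction). The average effects of DAC and of DEX over both backgrounds were also tested. For genes called on average, fry (limma 3.58.1) tested whether the effect differed with the other compound, each gene oriented by the sign of its average effect. With equal group sizes, the average contrasts and the interaction are orthogonal. With libraries left out they are not, so genes were there also chosen by an average whose weights, from the group sizes, restore this, a choice made after the data were seen. A gene was silent when every library of a group was below 0.1 CPM and expressed when every library reached 1 CPM.

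A total of 20 gene lists were written from general knowledge: cancer-testis and germline genes, interferon-stimulated genes, MHC class I antigen presentation, endogenous retrovirus-derived genes, glucocorticoid-induced genes, inflammatory genes repressed by glucocorticoids, G2/M, DNA replication, p53 targets, epithelial, mesenchymal, luminal and hormone receptor, epidermal differentiation, DNA methylation and decitabine metabolism, glucocorticoid receptor and cofactor, metallothionein, stress response, leukocyte and blood cell, fibroblast and endothelial, and neuronal genes. Some genes stand in several lists, such as DCN, LUM and COL1A2 in the mesenchymal and fibroblast lists. Lists were tested with camera (limma) at the preset correlation of 0.01, adjusted over 120 tests (20 lists in 6 contrasts). The camera test asks whether members changed more than other genes. For lists, fry asks another question, whether members changed at all. Where many genes change, a pass with fry alone does not set a list apart. Ranges over alternatives hold values of both tests. Members were counted after adjustment over all genes and over the list alone. Only members that passed the filter were tested and counted. Members with no read in a group passed it through the other groups, so against that group they could only be higher or unchanged.

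Genes named in the text follow a rule. It takes 9 fixed genes (DNMT1, NR3C1, FKBP5, TSC22D3, PER1, CDH1, VIM, CDKN1A and ESR1). In each contrast it adds the 6 largest rises and the 6 largest falls among protein-coding genes that were called, had a mean of 5 CPM or more in the higher group and had no overlap between the libraries of the groups compared. For each list mentioned it adds the 2 members with the smallest adjusted p in each direction or, where none was called, the 2 with the highest mean CPM. Other named genes are said to have been chosen after their values were seen. The groups, contrasts, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

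Totals per library ranged from 16814282 to 21234273 counts, so 3 counts in a library correspond to 0.1295 to 0.2443 CPM. This floor covers counting error only. A fold against a group with no read in any library is a lower bound computed from a floor of 3 counts per library. The analysis was tested on simulated data: of 66 genes changed 4-fold, 59.1%, 63.6%, 60.6%, 63.6%, 54.5% and 10.6% were recovered in the 6 contrasts in the order above, and of 67 genes changed 2-fold, 0 to 8.96% were. Few genes were changed in each of these simulations, so the adjusted threshold was stricter than in contrasts that called many genes. The shares recovered do not carry over to those contrasts. An oriented difference simulated at -0.75 was recovered as -0.703.

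The labels number the replicates of each group 1 to 3 without saying what a number shares. Deviations from the group means of same-numbered DAC and DAC+DEX libraries correlated at 0.296, 0.213 and 0.18 across genes, each over 0.1, so for this comparison the numbers were taken to pair the libraries, from the data and not from the labels, and the fit with the replicate number as a block is given beside it where it changes a call or a count. In each other comparison of 2 groups, at least 1 same-numbered pair correlated below 0.1. DAC and DEX were not compared with each other, but both enter the average effects and the interaction. Their same-numbered libraries correlated at 0.573, 0.28 and 0.674, and their differently numbered libraries at -0.664 to 0.497.

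Alternatives fixed beforehand were DESeq2 size factors in the edgeR fit, library totals alone, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of 1 CPM in 3 libraries, only the groups compared, the replicate number as a block, an adjusted p under 0.01, glmTreat against a fold of 1.5, each library left out in turn, an estimated correlation in camera, fry for the lists, and other limits for silent genes. Chosen after seeing the data were leaving out DAC replicate 3 and DEX replicate 3, leaving out these and DMSO replicate 3, an offset for gene length and GC content per library (a spline with 5 degrees of freedom), sample weights and, for DAC+DEX against DAC, the replicate block in those 6 libraries alone, without DAC replicate 3 and DEX replicate 3 or with the offset. Labels of libraries were used as deposited, and no library was moved to another group. No library was left out of the values in the report unless said so.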

Results

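Messenger RNA was sequenced from MDA-MB-231, an established human triple-negative breast cancer line grown from a pleural effusion. Cells were treated with vehicle (DMSO), DAC at 10 µM, DEX at 1 µM or DAC together with DEX, and were collected on day 6. DAC is the usual abbreviation of decitabine, an inhibitor of DNA methyltransferases, and DEX that of dexamethasone, a synthetic glucocorticoid. The sample labels spell out neither and do not restate the doses in the combined treatment. Each of the 4 groups held 3 libraries, numbered as replicates 1 to 3. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries held 16814282 (DEX replicate 3) to 21234273 counts (DMSO replicate 2). In the text, expression levels are mean CPM (counts scaled to library size) ± SD over 3 libraries, and log2 fold changes are given ± SE. Unless another test is named, adjusted p-values are from edgeR's quasi-likelihood test.

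More genes were detected after DAC. Between 15532 and 16075 genes reached 1 CPM in the DAC libraries and between 15194 and 15915 in the DAC+DEX libraries, against 13538 to 13641 in DMSO and 13293 to 13360 in DEX. A pair of libraries stood apart by gene length: the log2 difference between the longest genes (6795 bases of exon or more) and the shortest genes (2405 or fewer) was -1.08 in DAC replicate 3 and -1.10 in DEX replicate 3, against -0.23 to 0.62 in the other libraries. Ribosomal protein genes took 8.89% of the counts in DEX replicate 3, against 3.82% and 5.22% in DEX replicates 1 and 2, and 5.09% in DAC replicate 3, against 2.95% and 3.04% in DAC replicates 1 and 2. The library labelled DMSO replicate 3 carried glucocorticoid-induced transcripts at the level of the DEX group, as described with the DEX comparison. The numbers of higher and lower genes are therefore also given without these 3 libraries, an alternative chosen after seeing the data. The DMSO group then holds replicates 1 and 2 alone. Over all tested genes, DMSO replicate 1 lay further from DMSO replicates 2 and 3 (Pearson r of log2 CPM 0.9817 and 0.9755) than these lay from each other (0.9877).

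**Figure D1:**
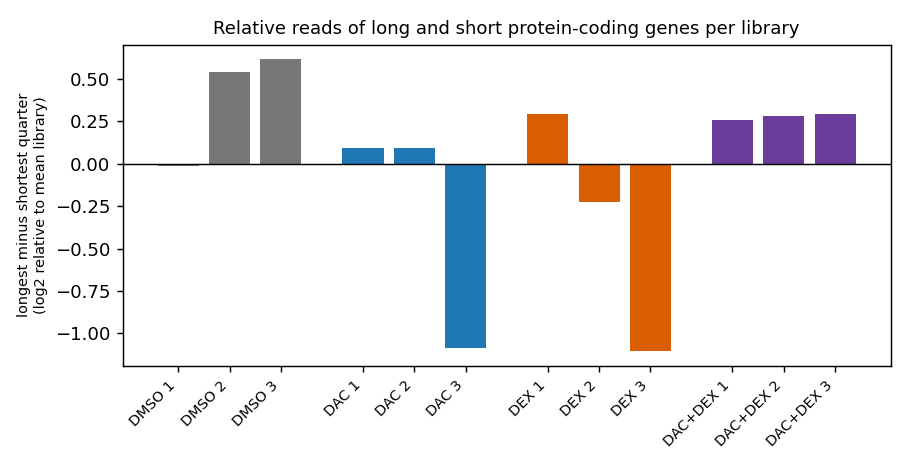
Each bar is 1 library and gives its log2 difference in level between the longest and the shortest genes, relative to the mean over all libraries. DAC replicate 3 (-1.08) and DEX replicate 3 (-1.10) lie below the other libraries, which range from -0.23 to 0.62.

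To determine which genes changed with DAC alone, DAC was compared with DMSO. DAZL, CXCL5 and TKTL1 were not detected in DMSO and rose with DAC. DAZL, an RNA-binding protein of germ cells (ENSG00000092345, GRCh38 chromosome 3, 16586792 to 16670306), had no read in any DMSO library and reached 102 ± 9.20 CPM with DAC, at least 640.2-fold higher (adjusted p = 9.56e-07). CXCL5, a neutrophil-attracting chemokine (ENSG00000163735, chromosome 4, 73995642 to 73998779), went from no read to 54.5 ± 28.2 CPM, at least 342-fold (adjusted p = 1.17e-05). TKTL1, a transketolase-like gene (ENSG00000007350, chromosome X, 154295671 to 154330350), went from no read to 36.8 ± 10.6 CPM, at least 232-fold (adjusted p = 6.80e-06). Among the falls named by the rule, that of CDH4, the gene of R-cadherin, ranked first (ENSG00000179242, chromosome 20, 61252426 to 61940617). It went from 139 ± 19.4 to 5.56 ± 1.19 CPM (log2 fold change -4.64 ± 0.35, adjusted p = 7.11e-06). The neural adhesion gene NEGR1 fell from 26.2 ± 4.97 to 3.20 ± 0.642 CPM (log2 -3.03 ± 0.27), and the lipoprotein receptor gene LRP8 from 86.9 ± 9.37 to 11.1 ± 4.32 CPM. The lipid transporter gene ATP10A fell by a log2 fold change of -3.07, or -2.31 without DMSO replicate 3. MAP2, a neuronal cytoskeleton gene, was lower (log2 -3.71, adjusted p = 0.0181) but not called without DMSO replicate 3 (-1.25, 0.213), DAC replicate 3 (-3.33, 0.068) or all 3 libraries that stood apart (-0.83, 0.347), nor with sample weights (0.0894), in a range of 6.68e-24 to 0.347.

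Of 18526 genes tested, 3607 were higher and 1736 lower with DAC than with DMSO, and 3255 and 907 of them differed at least 2-fold. Without the 3 libraries that stood apart, 4177 were higher and 2790 lower, 3408 and 886 of them at least 2-fold. The number of lower genes was 1156 without DMSO replicate 3, 1127 without DMSO replicate 2, 1145 without DAC replicate 1 and 2935 without DEX replicate 3. Higher genes made up 67.5% of the calls, and 86.3% when libraries were scaled by their total alone (4783 higher, 759 lower), which moved the median log2 fold change of all genes from 0.05 to 0.32. Among protein-coding genes, the median summed exon length was 3908 bases for higher genes, 6541 for lower genes and 5008 for all tested, beside the loss of long genes in DAC replicate 3. Among genes that do not code for protein, 1021 of 4055 were higher and 105 lower, and 1107 and 165 of 4317 without the 3 libraries. A group of 273 genes, 209 of them protein-coding, was silent in every DMSO library (below 0.1 CPM) and expressed in every DAC library (1 CPM or more), and no gene went the other way. The group held 358 genes without the 3 libraries, but leaving out libraries can only keep or raise this number, since every library must pass.

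**Figure D2:**
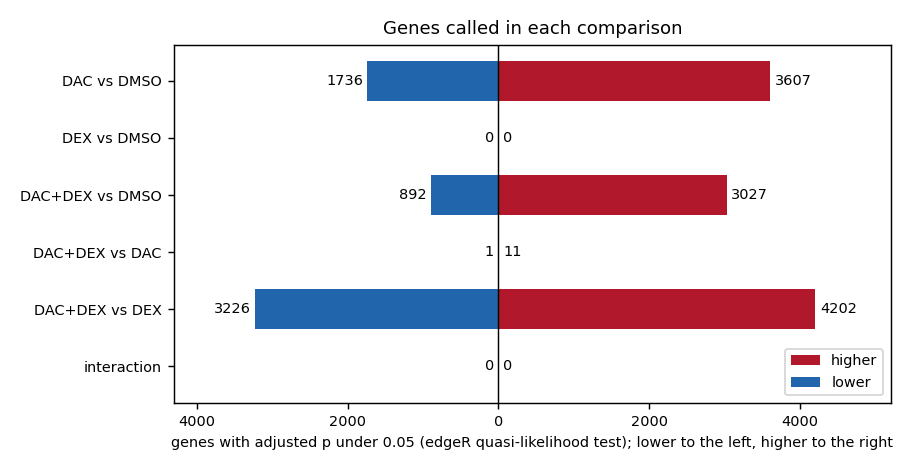
Each pair of bars gives the number of genes higher (right of 0) and lower (left of 0) in 1 comparison, at an adjusted p under 0.05. The comparisons of a DAC-treated group with a group without DAC hold 892 to 4202 genes per direction, and the others hold at most 11.

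Genes normally restricted to the testis or to tumours rose as a group. Of 40 in the list, 31 passed the filter, and 12 of these had no read in DMSO, so they could only rise or stay. Of the 31 cancer-testis and germline genes measured, 23 were higher and 1 was lower, over all genes and adjusted over the list alone, with a median log2 fold change of 7.03, or 4.17 with genes absent in DMSO set at their lower bound (camera adjusted p = 1.17e-27; adjusted p = 0.0417 with an estimated correlation). MAGEB2, a melanoma antigen family member, rose from 0.195 ± 0.0648 to 34.6 ± 7.41 CPM (log2 7.43 ± 0.47). VCX3B, a germ cell gene on the X chromosome, went from no read to 24.3 ± 14.0 CPM. Near-identical copies of VCX and MAGE genes could share reads, so values for single members are uncertain. Its copy VCX3A reached 15.6 ± 9.53 CPM and the skin gene CRCT1 23.4 ± 20.8 CPM, both from no read. With no read in DMSO, the fitted log2 values of VCX3B, VCX3A and CRCT1 depend on the fit and do not measure a fold. Without DAC replicate 3 they went from 11.89, 11.26 and 11.84 to 11.31, 10.63 and 10.80. Of 8 genes derived from endogenous retroviruses, 3 rose over all genes tested and 4 adjusted over the list alone (camera adjusted p = 0.0167; adjusted p = 0.275 with an estimated correlation). These included ERVV-2 (log2 4.53 ± 0.62) and ERVH48-1 (log2 3.10 ± 0.45), retroviral envelope genes at 4.22 ± 1.30 and 2.17 ± 0.770 CPM with DAC.

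Inflammatory genes known to be repressed by glucocorticoids rose with DAC. Of 34 measured, 28 were higher and 1 lower over all genes, and 29 and 1 adjusted over the list alone (median log2 3.995, camera adjusted p = 2.36e-23; adjusted p = 0.0247 with an estimated correlation). MMP3, a matrix-degrading protease, rose from 2.06 ± 0.926 to 164 ± 10.5 CPM (log2 6.31 ± 0.41) and CXCL1, a chemokine, from 1.99 ± 0.449 to 121 ± 39.5 CPM (log2 5.92 ± 0.40). Interferon-stimulated genes did not pass as a list (camera adjusted p = 0.125), although 15 of 45 rose over all genes, with CXCL11 at a log2 fold change of 3.77 ± 0.29. The list of MHC class I antigen presentation did not pass either (camera adjusted p = 0.0813), while 7 of 18 members rose, among them the peptide transporter TAP1 (71.2 ± 1.55 to 180.5 ± 22.6 CPM, log2 1.34 ± 0.18). Without DAC replicate 3 and DEX replicate 3, both of these lists passed (adjusted p = 0.0432 and 0.0400, within ranges over all alternatives of 0.0113 to 0.672 and 0.0128 to 0.647). The interferon list also passed without DMSO replicate 2 (0.0496) and the MHC list without DMSO replicate 1 (0.0413), DAC replicate 1 (0.0278) or DEX replicate 3 (0.0421).

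Cell cycle genes fell. Of 35 G2/M genes, 24 were lower and none higher over all genes, and 25 were lower adjusted over the list alone (median log2 -0.93, camera adjusted p = 9.84e-10; adjusted p = 0.0797 with an estimated correlation). The mitotic kinase PLK1 fell from 145 ± 12.8 to 48.0 ± 8.39 CPM (log2 -1.60 ± 0.21) and cyclin B1 (CCNB1) from 366 ± 20.4 to 167 ± 23.1 CPM (log2 -1.13 ± 0.18). Of 40 DNA replication genes, 11 were lower and 1 higher, and 12 and 1 adjusted over the list alone (camera adjusted p = 6.73e-05; adjusted p = 0.0597 with an estimated correlation), with the helicase subunits MCM6 and MCM5 at log2 -1.35 ± 0.20 and -1.50 ± 0.26. CDKN1A, the gene of the cell cycle inhibitor p21, rose from 57.7 ± 13.6 to 293 ± 74.2 CPM (log2 2.34 ± 0.28, adjusted p = 9.70e-05). The death receptor gene FAS rose by a log2 fold change of 1.89 ± 0.25. They were among 8 of 26 p53 target genes that rose, a list that did not pass with camera (adjusted p = 0.12) and passed with fry (adjusted p = 5.50e-05), in a range of 5.50e-05 to 0.242. The members thus changed, but not shown to be more than other genes, which only camera tests. DNMT1, the maintenance DNA methyltransferase, fell from 409 ± 30.2 to 231 ± 55.0 CPM (log2 -0.82 ± 0.20, adjusted p = 0.00774). In the list of DNA methylation and decitabine metabolism genes, 6 of 20 fell and 1 rose (camera adjusted p = 0.0139; adjusted p = 0.474 with an estimated correlation), with IDH1 at log2 -1.81 ± 0.33 and UHRF1, which recruits DNMT1 to replicating DNA, at -1.17 ± 0.26.

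**Figure D3:**
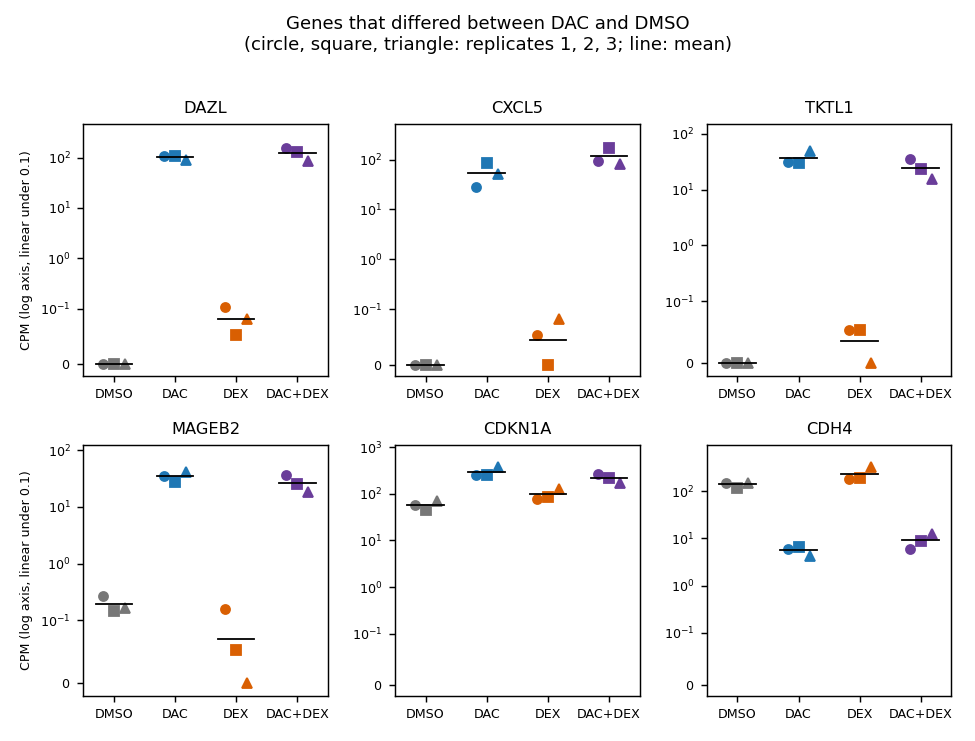
Normalised CPM per library (log scale, linear under 0.1 CPM) of DAZL, CXCL5, TKTL1, MAGEB2, CDKN1A and CDH4 in the 4 groups, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean. DAZL means were 102 CPM in DAC and 121 CPM in DAC+DEX against 0 in DMSO, and CDH4 means were 5.56 and 9.13 CPM against 139 in DMSO.

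Some genes of other lineages rose with DAC. Only 15 of 18 fibroblast and endothelial, 11 of 19 neuronal, 19 of 40 epidermal and 11 of 27 leukocyte members passed the filter. The others were not tested. Of those tested, 1, 2, 4 and 3 members in this order had no read in DMSO and could only rise or stay. Of 15 fibroblast and endothelial markers, 12 rose and none fell (median log2 2.70, camera adjusted p = 1.07e-09; adjusted p = 0.0417 with an estimated correlation), including the collagen gene COL1A2 (0.276 ± 0.147 to 5.75 ± 2.12 CPM). Among 11 neuronal markers, 6 rose and 1 fell (camera adjusted p = 1.94e-04; adjusted p = 0.102 with an estimated correlation), with the ubiquitin hydrolase gene UCHL1 going from 1 read in the DMSO group to 52.9 ± 9.97 CPM and the neurofilament gene INA from no read to 4.22 ± 0.877 CPM, at least 26.5-fold. Of 19 epidermal differentiation genes, 13 rose and 2 fell (median log2 3.33, or 2.63 with genes at their bound; camera adjusted p = 1.38e-05; adjusted p = 0.145 with an estimated correlation), with KRT17 at log2 4.75 ± 0.45 and KRT80 at -1.39 ± 0.26. Among 34 mesenchymal genes, 12 rose and 5 fell, with N-cadherin (CDH2) at log2 4.92 ± 0.37 and the receptor kinase gene AXL falling from 1460 ± 113 to 336 ± 49.7 CPM (log2 -2.12 ± 0.18). That list passed (camera adjusted p = 0.0209; adjusted p = 0.275 with an estimated correlation), but not without DMSO replicate 1 (0.0767) or DAC replicate 2 (0.0599), in a range over its alternatives of 4.29e-04 to 0.275. Of 11 leukocyte and blood cell markers, 4 rose (camera adjusted p = 0.0342; adjusted p = 0.208 with an estimated correlation), and the list did not pass without DAC replicate 3 (0.0621), DAC and DEX replicates 3 (0.0709) or all 3 libraries that stood apart (0.1), in a range of 2.89e-04 to 0.208.

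The remaining lists did not pass for DAC against DMSO. Of 37 epithelial genes, 12 rose (camera adjusted p = 0.115, and 0.0283 without DAC replicate 1, in a range of 0.0283 to 0.733), with CLDN7 at log2 1.90 ± 0.32. E-cadherin (CDH1) was at 16.2, 97.4 and 116 CPM in the DMSO libraries and 29.6 ± 10.5 CPM in DAC (adjusted p = 0.104, and 0.0104 without DMSO replicate 1, in a range of 2.23e-05 to 0.305). Of 44 glucocorticoid-induced genes, 6 rose and 2 fell (camera adjusted p = 0.939). Their mean log2 fold change was 0.19 while the test pointed down. It pointed up without DMSO replicate 3 (0.125), DAC replicate 1 (0.957) or all 3 libraries that stood apart (0.0557), and with fry (0.49), in a range of 0.0557 to 0.984. Among 23 luminal and hormone receptor genes, 4 rose and 3 fell (camera adjusted p = 0.989, the test pointing down and the median at 0.16), and the estrogen receptor gene ESR1 was at 0.259 to 0.691 CPM in the 4 groups. Among 18 glucocorticoid receptor and cofactor genes, 2 rose and 3 fell (camera adjusted p = 0.337), with HSD11B1, which regenerates active glucocorticoid, at log2 4.20 ± 0.38 and the corepressor NCOR1 at -1.03 ± 0.20. The glucocorticoid receptor gene NR3C1 was at 177 ± 42.7 CPM in DMSO and 121 ± 35.9 CPM in DAC (adjusted p = 0.178). Of 7 metallothionein genes, 2 rose (camera adjusted p = 0.946), and of 25 stress response genes 3 rose and 2 fell (camera adjusted p = 0.171, and 0.0343 without the 3 libraries that stood apart, in a range of 0.0343 to 0.681), with ATF3 at log2 2.26 ± 0.39 and DDIT4 at -2.88 ± 0.32.

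Next, DEX was compared with DMSO. Classical glucocorticoid-induced genes were high in every DEX library and also in the library labelled DMSO replicate 3. FKBP5, a co-chaperone of the glucocorticoid receptor, measured 87.1, 81.2 and 457 CPM in the libraries labelled DMSO replicates 1, 2 and 3, and 454, 377 and 224 CPM in DEX. TSC22D3, which encodes the leucine zipper protein GILZ, measured 9.41, 11.1 and 84.3 CPM against 89.9, 76.5 and 114 CPM, and PER1, a circadian clock gene, 11.1, 10.4 and 52.1 CPM against 61.0, 67.4 and 98.3 CPM. ZBTB16, singled out after its values were seen, had no read in DMSO replicates 1 and 2, 3.20 CPM in the library labelled DMSO replicate 3 and 5.43 to 9.12 CPM in DEX. With all 12 libraries, FKBP5, TSC22D3 and PER1 did not pass the test (log2 0.75 ± 0.60, 1.42 ± 0.65 and 1.62 ± 0.50; adjusted p = 0.449, 0.239 and 0.197).

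**Figure D4:**
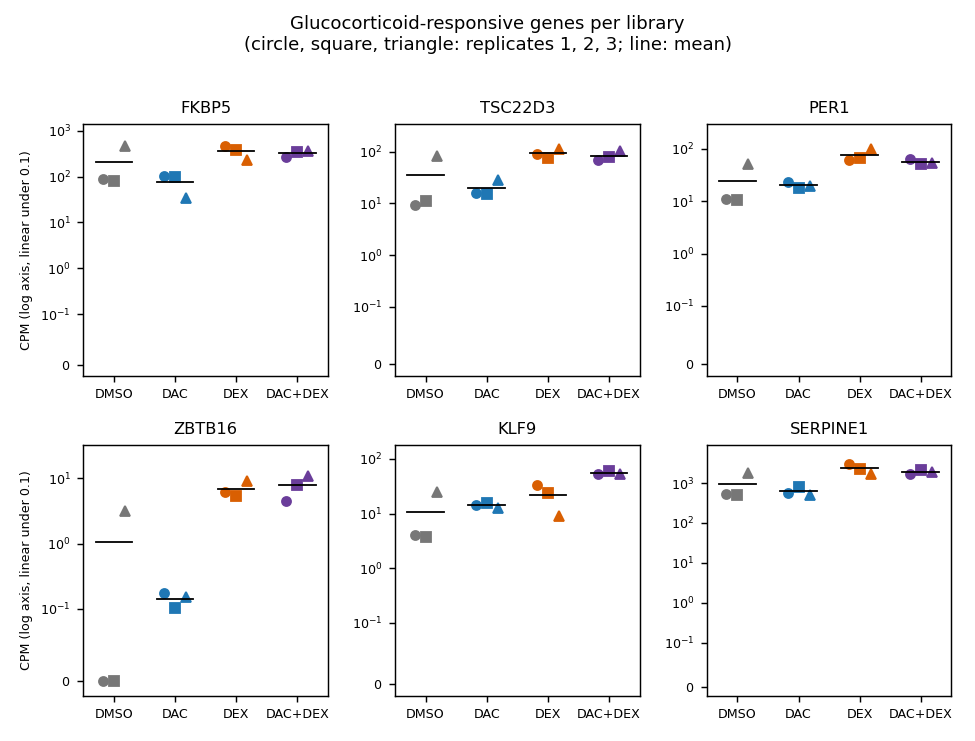
Normalised CPM per library (log scale, linear under 0.1 CPM) of 6 glucocorticoid-regulated genes in the 4 groups, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean. The triangle of the DMSO group lies above the DEX libraries for FKBP5 (457 CPM against 224 to 454) and away from the other DMSO libraries (81.2 and 87.1).

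No gene passed an adjusted p of 0.05 for DEX against DMSO in edgeR, in either direction, while 3878 genes had an unadjusted p under 0.05 (2422 higher, 1456 lower) and the lowest adjusted p was 0.0524. DESeq2 called 210 genes higher and 291 lower, and limma-voom called 0. Without the 3 libraries that stood apart, 197 genes were higher and 314 lower, among them FKBP5 (log2 2.30 ± 0.18), TSC22D3 (3.01 ± 0.21), PER1 (2.58 ± 0.19) and MT2A (2.22 ± 0.30), with adjusted p-values of 5.70e-05, 3.41e-05, 5.65e-05 and 0.00239. Over all alternatives, these ranged from 5.70e-05 to 0.83 for FKBP5, 3.41e-05 to 0.594 for TSC22D3, 2.58e-05 to 0.569 for PER1 and 5.27e-16 to 0.542 for MT2A. With single libraries left out, counts of higher and lower genes were 68 and 89 without DMSO replicate 3, 6 and 49 without DMSO replicate 1, 0 and 1 without DMSO replicate 2, and 1209 and 500 without DEX replicate 1.

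As a list, the 44 glucocorticoid-induced genes were higher with DEX than in the DMSO group, library labelled DMSO replicate 3 included (median log2 0.77, camera adjusted p = 2.73e-06; adjusted p = 0.192 with an estimated correlation), with 0 genes passing over all genes and 12 higher and 3 lower adjusted over the list alone. BIRC3, an inhibitor of apoptosis, measured 199 ± 207 CPM in DMSO and 345 ± 54.8 CPM in DEX (adjusted p = 0.395, and 0.0347 without DMSO replicate 3, in a range of 0.00343 to 0.751). The 7 metallothionein genes, which bind metals, were also higher (median log2 2.17, camera adjusted p = 4.00e-06; adjusted p = 0.122 with an estimated correlation), 5 of them adjusted over the list alone. MT2A measured 968, 1593 and 4706 CPM in DEX replicates 1, 2 and 3, with its highest value in the library that had lost long genes, and metallothionein copies could share reads. Interferon-stimulated genes were lower (median log2 -0.39, camera adjusted p = 2.49e-04; adjusted p = 0.292 with an estimated correlation), 10 of 45 adjusted over the list alone. Epidermal differentiation genes were higher (median log2 1.01, or 0.05 with genes at their bound; camera adjusted p = 0.0108; adjusted p = 0.393 with an estimated correlation), but not without DMSO replicate 1 (0.0516), with fry (0.128) or with an offset for gene length and GC content (0.0779), in a range of 7.66e-04 to 0.393. Inflammatory genes did not pass with all libraries (camera adjusted p = 0.451), although 2 were higher and 7 lower adjusted over the list alone. They were lower without DMSO replicate 3 (0.015) and without all 3 libraries that stood apart (0.0265), in a range of 0.015 to 0.953. MMP1, a collagenase, measured 467, 552 and 217 CPM in the libraries labelled DMSO and 70.3, 90.2 and 166 CPM in DEX (adjusted p = 0.112). It was lower without DMSO replicate 3 (0.0179) or DEX replicate 1 (0.0443), in a range of 4.00e-10 to 0.507. Epithelial genes did not pass with all libraries (camera adjusted p = 0.0958) and were lower without the 3 libraries (3.76e-06), DMSO replicate 1 (0.0118) or DEX replicate 3 (4.45e-07), in a range of 1.79e-07 to 0.721, with CDH1 at 21.5 ± 7.04 CPM in DEX. Luminal and hormone receptor genes (camera adjusted p = 0.249) were lower without the 3 libraries (0.00115) or DEX replicate 3 (0.00416), in a range of 0.00115 to 0.611.

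To see the effect of both compounds together, DAC+DEX was compared with DMSO. DAZL reached 121 ± 34.8 CPM and CXCL5 116 ± 47.7 CPM, at least 761-fold and 727-fold higher than in DMSO, where neither had a read. PGC, the gene of the digestive enzyme precursor pepsinogen C, and MME, the gene of the membrane peptidase neprilysin, also went from no read to 14.5 ± 5.26 and 13.9 ± 2.78 CPM, at least 90.9-fold and 87.2-fold. CDH4 fell (log2 -3.93 ± 0.33). So did CALB2, the gene of the calcium-binding protein calretinin (68.9 ± 19.1 to 9.24 ± 1.20 CPM, log2 -2.90 ± 0.47, adjusted p = 9.39e-04), the neural adhesion gene NEGR1 (log2 -2.54 ± 0.26) and the sorting receptor gene SORCS2 (log2 -2.62 ± 0.33). TKTL1 and VCX3B were at least 153.5-fold and 89.7-fold higher. The myosin gene MYH15 fell by a log2 fold change of -2.59, or -1.81 without DMSO replicate 2. SPNS2, a lipid transporter gene, fell (log2 -2.76, adjusted p = 0.0117), but not without DMSO replicate 2 (-1.98, 0.0574) or DAC+DEX replicate 1 (0.0533), in a range of 8.71e-17 to 0.0574.

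In this comparison 3027 genes were higher and 892 lower, and without the 3 libraries that stood apart 4386 and 2949. The number of lower genes was 547 without DMSO replicate 1, 557 without DMSO replicate 2, 1908 without DEX replicate 3, 370 without DAC+DEX replicate 1 and 530 without DAC+DEX replicate 2. Higher genes made up 77.2% of the calls, and 89.2% (3637 higher, 442 lower) with library totals alone, which moved the median of all genes from 0.05 to 0.24.

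Cancer-testis and germline genes rose (23 of 31 higher and 1 lower, median log2 6.14, or 3.64 with genes at their bound; camera adjusted p = 2.06e-27; adjusted p = 0.0545 with an estimated correlation). So did inflammatory genes (23 of 34 higher and 2 lower, median log2 2.93, camera adjusted p = 3.43e-15; adjusted p = 0.0417 with an estimated correlation) and fibroblast and endothelial markers (13 of 15, median log2 2.95, camera adjusted p = 1.34e-16; adjusted p = 0.0247 with an estimated correlation). CXCL1 rose by a log2 fold change of 5.80 ± 0.40, and LUM, a small proteoglycan gene, by 4.09 ± 0.36. Interferon-stimulated genes passed here (17 of 45 higher over all genes, 22 adjusted over the list alone; camera adjusted p = 2.87e-05; adjusted p = 0.244 with an estimated correlation), with CXCL11 at log2 3.89 ± 0.29. Glucocorticoid-induced genes were higher against a DMSO group that includes the library labelled DMSO replicate 3 (14 of 44 over all genes, 17 adjusted over the list alone; median log2 0.59, camera adjusted p = 4.84e-04; adjusted p = 0.337 with an estimated correlation). The G-protein regulator gene RGS2 rose from 3.24 ± 1.84 to 37.9 ± 4.02 CPM (log2 3.55 ± 0.39) and STOM at log2 2.77 ± 0.29. Epidermal differentiation genes rose (15 of 19 higher and 2 lower, median log2 4.56, or 2.76 with genes at their bound; camera adjusted p = 1.62e-10; adjusted p = 0.0652 with an estimated correlation), KRT17 by log2 5.07 ± 0.45. Mesenchymal genes passed with 14 of 34 higher and 3 lower (camera adjusted p = 5.57e-04; adjusted p = 0.144 with an estimated correlation). VIM, the gene of vimentin, which is counted in that list, fell from 1373 ± 481 to 573 ± 78.0 CPM (log2 -1.26 ± 0.28, adjusted p = 0.00651), and AXL fell by log2 -1.87 ± 0.18.

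G2/M genes fell (8 of 35, median log2 -0.60, camera adjusted p = 1.86e-06; adjusted p = 0.145 with an estimated correlation), PLK1 by log2 -1.39 ± 0.21. DNA replication genes fell (6 of 40, camera adjusted p = 5.54e-05; adjusted p = 0.0597 with an estimated correlation), MCM5 by log2 -1.38 ± 0.26. CDKN1A rose to 218 ± 44.1 CPM (log2 1.92 ± 0.27, adjusted p = 3.95e-04). DNMT1 was at 259 ± 6.52 CPM (log2 -0.66 ± 0.20, adjusted p = 0.0299), a call that did not hold without DMSO replicate 1 (0.0571), DMSO replicate 2 (0.0757) or DAC+DEX replicate 1, 2 or 3 (0.0717, 0.0638 and 0.0514), nor with library totals alone (0.0964) or without a filter (0.0691). Over all alternatives its adjusted p ranged from 2.38e-05 to 0.0964. Endogenous retrovirus genes passed (6 of 8 higher, camera adjusted p = 0.00233; adjusted p = 0.154 with an estimated correlation), as did neuronal markers (5 of 11, camera adjusted p = 3.54e-04; adjusted p = 0.122 with an estimated correlation). The lists of p53 targets (camera adjusted p = 0.177), MHC class I (0.258) and epithelial genes (0.108) did not pass. With fry, p53 targets (6.42e-05, in a range of 6.42e-05 to 0.292) and MHC class I (0.0347, in a range of 0.0347 to 0.733) did. Epithelial genes passed with the length and GC offset (0.0467, in a range of 0.0467 to 0.728).

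To ask what DEX added to DAC, DAC+DEX was compared with DAC. A small group of genes at mean levels of 0.0335 to 2.06 CPM with DAC alone was higher with both compounds, at 1.77 to 56.4 CPM. KRT6A, a keratin of activated epidermis (ENSG00000205420, chromosome 12, 52487174 to 52493257), rose from 0.0989 ± 0.0550 CPM with DAC to 56.4 ± 7.23 CPM with DAC+DEX (log2 9.10 ± 0.47, adjusted p = 1.83e-06) and measured 0.851 ± 0.322 CPM with DEX alone. DCN, the gene of the matrix proteoglycan decorin (ENSG00000011465, chromosome 12, 91140484 to 91183123), rose from 0.619 ± 0.202 to 35.9 ± 13.5 CPM (log2 5.86 ± 0.48, adjusted p = 2.47e-04). HAL, the histidine-degrading enzyme (ENSG00000084110, chromosome 12, 95972662 to 95996365), rose from 0.688 ± 0.0565 to 8.86 ± 2.27 CPM (log2 3.68 ± 0.35, adjusted p = 7.22e-04). MMP3 (ENSG00000149968, chromosome 11, 102835801 to 102843803) had risen with DAC. It was lower with both, at 22.4 ± 9.11 against 164 ± 10.5 CPM (log2 -2.87 ± 0.34, adjusted p = 0.00408).

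In all, 11 genes were higher and 1 lower by edgeR, 1700 genes had an unadjusted p under 0.05 (995 higher, 705 lower), and DESeq2 called 146 and 58 and limma-voom 51 and 10. Setting aside the 3 libraries that stood apart gave 240 higher and 75 lower. Same-numbered DAC and DAC+DEX libraries deviated together, and with the replicate number as a block 24 genes were higher and 2 lower. Of the 12 genes, 11 were also called in that fit, and MUCL3 was not (0.0512). A block fitted to the DAC and DAC+DEX libraries alone, chosen after seeing the data, gave 65 and 15 and did not call ENSG00000248187 (log2 5.53, adjusted p = 0.0733, in a range of 1.99e-09 to 0.148). Counts without the block were 17 and 3 without DMSO replicate 2, 74 and 13 without DMSO replicate 3, 3 and 1 without DAC replicate 1, 4 and 1 without DAC replicate 2, 17 and 1 without DEX replicate 1, 70 and 18 without DEX replicate 3, and 6 and 1, 6 and 0, and 7 and 1 without DAC+DEX replicates 1, 2 and 3. The other genes under the naming rule were PGC (log2 5.16 ± 0.54, adjusted p = 0.00408), the muscle protein gene MYOM1 (log2 3.62 ± 0.41, adjusted p = 0.00363) and the complement receptor gene C5AR2 (log2 3.15 ± 0.48, adjusted p = 0.0331). PGC was not called without DAC replicate 1 (0.0738), MYOM1 without DAC replicate 1 or 2 (0.0518 and 0.06) and MMP3 without DAC+DEX replicate 2 (0.0533), in ranges over their alternatives of 8.94e-25 to 0.0738, 4.36e-24 to 0.06 and 4.62e-17 to 0.0533. C5AR2 was not called without DAC replicate 1, 2 or 3 (0.23, 0.243 and 0.121), DAC+DEX replicate 1, 2 or 3 (0.121, 0.21 and 0.167), DMSO replicate 1 (0.0512) or DEX replicate 2 (0.0567), in a range of 2.44e-12 to 0.243. Chosen after their values were seen, the remaining genes were BEST2 (log2 2.75 ± 0.31), TGM4 (2.22 ± 0.31), MUCL3 (3.66 ± 0.46), the intergenic transcript ENSG00000248187 (5.53 ± 0.75) and the antisense transcript ENSG00000232909 (2.70 ± 0.36). Reads of the last cannot be told from those of its partner because the strand setting is not given. The highest adjusted p over all alternatives was 0.0615, 0.181, 0.276, 0.148 and 0.138 for these 5 genes in this order.

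**Figure D5:**
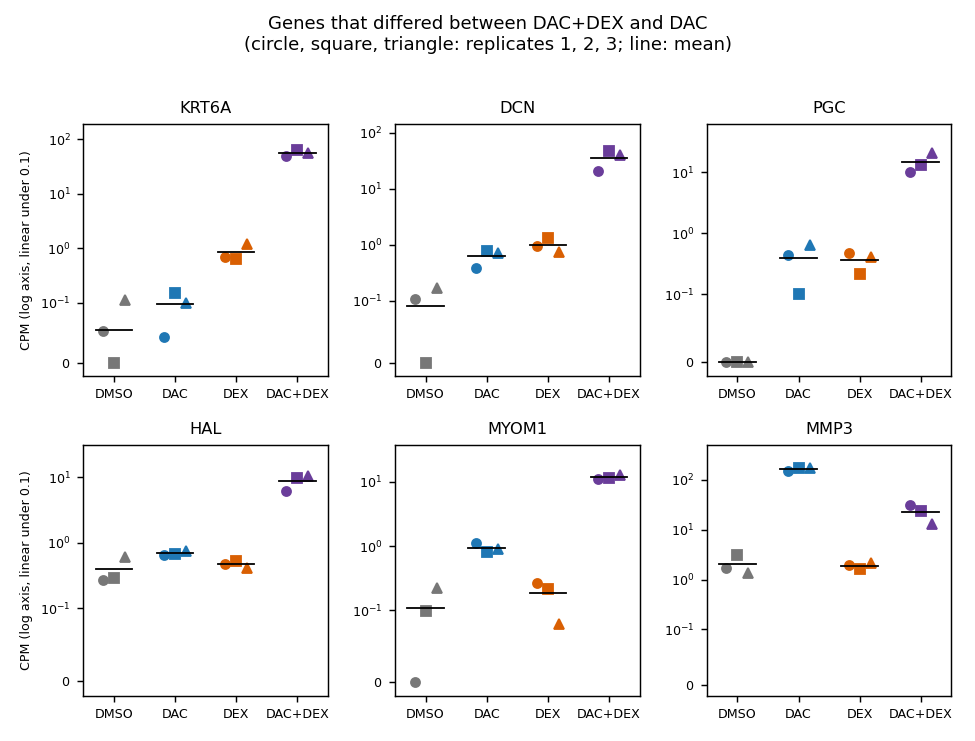
Normalised CPM per library (log scale, linear under 0.1 CPM) of KRT6A, DCN, PGC, HAL, MYOM1 and MMP3 in the 4 groups, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean. KRT6A means were 0.0553, 0.0989, 0.851 and 56.4 CPM in DMSO, DAC, DEX and DAC+DEX, and MMP3 means were 2.06, 164, 1.90 and 22.4 CPM.

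Glucocorticoid-induced genes were higher with DAC+DEX than with DAC as a list (median log2 0.91, camera adjusted p = 9.19e-15; adjusted p = 0.0797 with an estimated correlation), 0 of 44 over all genes and 18 adjusted over the list alone. FKBP5 measured 322 ± 48.1 against 77.9 ± 38.1 CPM (log2 2.05 ± 0.62, adjusted p = 0.313), TSC22D3 84.2 ± 16.3 against 20.1 ± 7.79 CPM (log2 2.07 ± 0.67, adjusted p = 0.364) and PER1 56.0 ± 6.56 against 20.3 ± 2.93 CPM (log2 1.46 ± 0.50, adjusted p = 0.406). Without the 3 libraries that stood apart, all 3 genes passed (adjusted p = 3.88e-04, 1.37e-04 and 0.00133, in ranges of 1.62e-10 to 0.858, 1.12e-09 to 0.862 and 1.15e-04 to 0.862). With the block in the DAC and DAC+DEX libraries alone, TSC22D3 and PER1 passed (0.0251 and 0.0325). BIRC3 measured 2103 ± 245 CPM with both against 388 ± 109 CPM with DAC (adjusted p = 0.167), and was higher without DMSO replicate 3 (0.00859) and with that block (0.0188), in a range of 1.13e-15 to 0.61. Inflammatory genes were lower as a list (median log2 -0.92, camera adjusted p = 3.59e-11; adjusted p = 0.0597 with an estimated correlation), 1 over all genes and 13 adjusted over the list alone. Interferon-stimulated genes were higher (median log2 0.54, camera adjusted p = 4.16e-06; adjusted p = 0.199 with an estimated correlation), 0 of 45 over all genes and 2 adjusted over the list alone. So were G2/M genes (median log2 0.34, camera adjusted p = 3.54e-04; adjusted p = 0.267 with an estimated correlation), fibroblast and endothelial markers (median log2 0.32, camera adjusted p = 0.00119; adjusted p = 0.144 with an estimated correlation) and epidermal differentiation genes (median log2 0.23, camera adjusted p = 0.00251; adjusted p = 0.292 with an estimated correlation). Of 35 G2/M genes, 0 were called over all genes or over the list alone. Of 15 fibroblast and endothelial markers, 1 was called either way. Of 19 epidermal genes, 1 was called over all genes and 2 over the list alone. Metallothionein genes passed at a median log2 of 0.56 (camera adjusted p = 0.0376; adjusted p = 0.438 with an estimated correlation), but not without DAC replicate 1 (0.137), DAC replicate 2 (0.0971) or DAC+DEX replicate 2 (0.0719), or with fry (0.183), in a range of 4.88e-05 to 0.438. Cancer-testis genes were lower (median log2 -0.44, camera adjusted p = 0.00509; adjusted p = 0.517 with an estimated correlation), but not without DAC+DEX replicate 3 (0.283), with fry (0.179) or with the length and GC offset (0.0542), in a range of 1.67e-04 to 0.517. Of 31 members, 0 were called over all genes, and 1 was higher and 0 lower over the list alone. With fry, epidermal genes did not pass either (0.0812, in a range of 4.67e-08 to 0.292). DNA methylation genes (median log2 0.16, camera adjusted p = 0.0459; adjusted p = 0.581 with an estimated correlation) did not pass without DMSO replicate 3 (0.0589), DAC replicate 3 (0.296), DAC+DEX replicate 1, 2 or 3 (0.05, 0.0714 and 0.0516), DAC and DEX replicates 3 (0.263) or all 3 libraries that stood apart (0.329). They did not pass with fry (0.167), DESeq2 size factors (0.0626), the CPM filter (0.0746), the replicate block (0.0585) or the length and GC offset (0.259) either, in a range of 0.0155 to 0.581. Leukocyte markers (median log2 -0.54, camera adjusted p = 0.0343; adjusted p = 0.212 with an estimated correlation) did not pass without DMSO replicate 3 (0.0551), DAC replicate 2 (0.0971), DEX replicate 1 (0.0525), DAC+DEX replicate 1, 2 or 3 (0.0735, 0.052 and 0.0823), DAC and DEX replicates 3 (0.0522) or all 3 libraries that stood apart (0.0704). They did not pass with fry (0.0735), DESeq2 size factors (0.05), the replicate block (0.0873) or the length and GC offset (0.0635) either, in a range of 0.00615 to 0.212.

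DAC+DEX was then compared with DEX, which asks for the effect of DAC in the presence of DEX. DAZL rose from 0.0804 ± 0.0267 CPM with DEX to 121 CPM (log2 10.45 ± 0.41, adjusted p = 7.56e-07), and KRT6A rose by a log2 fold change of 6.08 ± 0.38. BEX1 and PNMA5, both on the X chromosome, had no read with DEX and reached 13.5 ± 4.78 and 15.3 ± 5.24 CPM, at least 72.0-fold and 81.3-fold higher. The X-linked antigen gene XAGE3, whose family copies could share reads, went from no read to 10.8 ± 3.00 CPM, at least 57.6-fold. UCHL1, with 1 read in the DEX group, reached 37.9 ± 13.5 CPM. CDH4 fell from 231 ± 80.2 to 9.13 ± 3.26 CPM (log2 -4.66 ± 0.35, adjusted p = 7.71e-06).

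Here 4202 genes were higher and 3226 lower, and without the 3 libraries that stood apart 5259 and 3646. The number of lower genes was 1855 without DAC+DEX replicate 1 and 2099 without DAC+DEX replicate 2. Higher genes made up 56.6% of the calls, and 78.7% (5962 higher, 1616 lower) with library totals alone, which moved the median of all genes from 0.19 to 0.53. After CDH4, the largest falls were those of genes that were highest in DEX replicate 3, the library that had lost long genes. They were MRPL12 and MRPL23, genes of mitochondrial ribosomal proteins, the mitochondrial carrier gene SLC25A10, the RNA polymerase subunit gene POLR2I and TGFBR3L, at log2 -3.30, -3.10, -3.22, -3.14 and -3.13 with all libraries and -1.97, -1.93, -2.06, -1.77 and -1.90 without DEX replicate 3. MRPL12 measured 29.2, 53.3 and 230 CPM in DEX replicates 1, 2 and 3. The summed exon lengths of these 5 genes were 1028 to 2975 bases, against a median of 5008 for tested coding genes.

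Inflammatory genes (27 of 34 higher, median log2 3.12, camera adjusted p = 1.19e-14; adjusted p = 0.0417 with an estimated correlation) and fibroblast and endothelial markers (13 of 15 higher, median log2 4.06, camera adjusted p = 1.92e-14; adjusted p = 0.0247 with an estimated correlation) rose, CXCL1 by log2 4.34 ± 0.37, while COL1A2 went from 0.0355 CPM (2 reads) to 4.46 ± 0.267 CPM. Cancer-testis genes rose (22 of 31 higher and 1 lower, median log2 5.15, or 4.30 with genes at their bound; camera adjusted p = 4.12e-18; adjusted p = 0.0823 with an estimated correlation). Interferon-stimulated genes rose (32 of 45 higher and 1 lower, median log2 1.44, camera adjusted p = 1.81e-08; adjusted p = 0.144 with an estimated correlation), with CXCL11 at log2 4.18 ± 0.30. The lysosomal transporter gene SLC46A3, a member of the glucocorticoid-induced list, rose by log2 2.06 ± 0.24. Epithelial genes passed with 19 of 37 higher and 5 lower (median log2 1.40, camera adjusted p = 0.0167; adjusted p = 0.647 with an estimated correlation), CLDN1 by log2 2.41 ± 0.37 and the epithelial transcription factor gene GRHL1 by 2.56 ± 0.31. That list did not pass without DEX replicate 1 (0.12), DEX replicate 2 (0.0503) or DAC+DEX replicate 3 (0.0526), in a range of 9.62e-05 to 0.647. Mesenchymal genes passed (14 of 34 higher and 3 lower, camera adjusted p = 7.37e-04; adjusted p = 0.143 with an estimated correlation), SPARC by log2 5.53 ± 0.45, while VIM fell (log2 -1.43 ± 0.28, adjusted p = 0.00236). Epidermal genes (14 of 19 higher and 2 lower, camera adjusted p = 8.01e-06; adjusted p = 0.144 with an estimated correlation), neuronal markers (6 of 11 higher, camera adjusted p = 5.77e-04; adjusted p = 0.129 with an estimated correlation) and retrovirus-derived genes (5 of 8 higher, camera adjusted p = 0.0174; adjusted p = 0.306 with an estimated correlation) also passed.

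G2/M genes fell (11 of 35, median log2 -0.37, camera adjusted p = 0.00153; adjusted p = 0.322 with an estimated correlation), the mitotic activator gene CDC20 by log2 -1.73 ± 0.27. DNA replication genes also fell (14 of 40, camera adjusted p = 2.04e-04; adjusted p = 0.0652 with an estimated correlation), MCM5 by -1.76 ± 0.27. DNMT1 (log2 -0.60 ± 0.20, adjusted p = 0.0294) was not called without DEX replicate 2 or 3 (0.056 and 0.059), without DAC+DEX replicate 1, 2 or 3 (0.0859, 0.0793 and 0.0653), with library totals alone (0.339) or without a filter (0.106), in a range of 2.15e-05 to 0.339. Glucocorticoid-induced genes did not pass as a list (camera adjusted p = 0.545), with 9 of 44 higher and 4 lower, and FKBP5 was at 322 ± 48.1 against 352 ± 117 CPM (adjusted p = 0.881). MT2A was lower (352 ± 27.4 against 2422 ± 2003 CPM, log2 -2.78 ± 0.57, and -1.87 without DEX replicate 3). CDKN1A rose (log2 1.17 ± 0.27, adjusted p = 0.00541), as did the p53 target gene TP53INP1 (log2 2.40 ± 0.33). The p53 target list passed with fry alone (5.50e-05, in a range of 5.50e-05 to 0.393), and the MHC class I list (camera adjusted p = 0.433) passed without the 3 libraries that stood apart (0.0221, in a range of 0.0204 to 0.775).

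Finally, the effect of DEX with DAC was set against its effect without DAC. No gene passed the interaction test in edgeR (lowest adjusted p = 0.193), while 4260 genes had an unadjusted p under 0.05 (1881 above 0, 2379 below 0). DESeq2 called 57 and 26 and limma-voom 0. Without DEX replicate 1, 580 and 1094 genes passed, and without the 3 libraries that stood apart 1 gene passed, SLCO4A1, an organic anion transporter gene chosen after its value was seen (log2 difference 3.46 ± 0.27, adjusted p = 4.25e-04). With all libraries, DMSO replicate 3 included, FKBP5, TSC22D3 and PER1 did not pass (log2 difference 1.29 ± 0.84, 0.65 ± 0.91 and -0.16 ± 0.70; adjusted p = 0.338, 0.657 and 0.905). Without the 3 libraries that stood apart, all these differences were negative (-0.61 ± 0.23, -0.58 ± 0.27 and -1.15 ± 0.25). They did not pass either (adjusted p = 0.447, 0.488 and 0.188), so the direction for FKBP5 and TSC22D3 depends on these libraries.

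On average over both backgrounds, DEX raised 55 genes and lowered 38 (394 and 367 without the 3 libraries that stood apart). The median log2 change of these 93 genes was 2.13 without DAC and 1.62 with DAC, and the median of the difference was -0.31. By fry at a threshold of 0.05, the difference did not pass with all libraries. It passed at -0.491 without the 3 libraries that stood apart and at -0.709 without DMSO replicate 3, and passed under no other alternative with the plain choice of genes. It was above 0 without DAC replicate 2 (0.749), DAC replicate 3 (0.0133), DEX replicate 2 (2.69) or DAC+DEX replicate 1, 2 or 3 (0.387, 3.72 and 0.0818). With unequal groups, this choice of genes by itself shifts the difference. With genes chosen by an average weighted for group size, it passed at -0.439 and -0.621 in the same 2 fits and in none of the other 12 with libraries left out. It was then above 0 without DMSO replicate 1 or 2 (0.0466 and 0.464), DEX replicate 2 (0.506) or DAC+DEX replicate 2 (3.72). These medians covered only 61, 30, 17 and 2 genes in this order, against 93 with all libraries. With the plain choice, too, the number of genes changed with the libraries left out. DAC raised 4986 genes and lowered 3363 on average (6234 and 4526 without the 3 libraries), with a median of 1.07 without DEX and 1.35 with DEX, a difference of 0.18 that did not pass by fry. Of the alternatives run, it passed only without DEX replicate 1, at 0.439 (0.352 with the weighted choice of genes). Of the genes changed on average by each compound, 63 were shared. Both compounds raised 28 and lowered 0 of these, DAC raised and DEX lowered 28, and DAC lowered and DEX raised 7, where independent lists would share 14.8, 6.90, 10.2 and 9.98 genes. The shared number was 32, 19 and 207 without DMSO replicates 1, 2 and 3, 17, 3 and 28 without DAC replicates 1, 2 and 3, 3 without DEX replicate 2, 18, 2 and 14 without DAC+DEX replicates 1, 2 and 3, and 519 without the 3 libraries that stood apart. It was 122 with the replicate block, 176 with the length and GC offset and 112 without DAC and DEX replicates 3. At an adjusted p under 0.01 it was 2.

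Across 18526 genes, log2 changes with DAC without and with DEX correlated at a Pearson r of 0.81 (Spearman 0.562, covariance 2.52), where simulated unchanged groups gave -0.00331 and a covariance of -5.64e-04. The changes with DEX without and with DAC correlated at -0.0988 (Spearman -0.326, covariance -0.0506), against 2.65e-04 and 5.23e-05 in the simulation, and at 0.278 (Spearman 0.0817, covariance 0.141) without the 3 libraries that stood apart. These correlations are across genes, which are not independent replicates. The simulation drew genes independently, without deviations shared between libraries, so its values lie near 0 by construction. It also used means of log2 CPM in place of fitted log2 changes. Real libraries shared deviations, such as DAC and DEX replicates 3 (0.674). Their part in these correlations was not tested. With the 3 libraries left out, 109 genes were higher with DEX both without and with DAC, and 37 were lower in both, where independent lists would share 2.49 and 1.24. Of 120 list tests over the 6 contrasts, 53 passed with the preset correlation. With an estimated correlation 7 held, namely cancer-testis genes for DAC against DMSO and inflammatory genes and fibroblast and endothelial markers for each of the 3 comparisons of a DAC-treated group with DMSO or DEX.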

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

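Chosen after the results were seen were all tests of the library labelled DMSO replicate 3, all tests of the genes that differed between DAC+DEX and DAC, the gaps of the length-skewed libraries, the fits with the replicate block and fewer libraries, and every value without the 3 libraries that stood apart. The weighed patterns were noticed in these data, so explanations left open are hypotheses.

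For 6 gene lists, the test of the difference between the DEX effects with and without DAC passed at the preset correlation, and all 6 include the library labelled DMSO replicate 3 in the effect without DAC. Interferon-stimulated genes had a median log2 difference of 0.885 (camera adjusted p = 1.42e-07; adjusted p = 0.145 with an estimated correlation), and 1.01 without the 3 libraries that stood apart (4.43e-23). Inflammatory genes were at -0.569 (0.0183; adjusted p = 0.409 with an estimated correlation), and did not pass without DMSO replicate 3 (0.0622), DAC replicate 2 (0.0688) or DEX replicate 1 (0.161), with the length and GC offset (0.172) or with fry (0.167), in a range of 0.00155 to 0.409. G2/M genes were at 0.525 (0.00222; adjusted p = 0.337 with an estimated correlation), and 0.29 without the 3 libraries. DNA methylation genes were at 0.413 (0.0367; adjusted p = 0.562 with an estimated correlation), and did not pass without DAC replicate 3 (0.0835), DAC and DEX replicates 3 (0.15) or the 3 libraries (0.144), or with the length and GC offset (0.267), fry (0.0847) or DESeq2 size factors (0.05), in a range of 0.0155 to 0.562. Metallothionein genes were at -1.51 (0.0304; adjusted p = 0.412 with an estimated correlation), and did not pass without DMSO replicate 2 (0.0582), DAC+DEX replicate 1 (0.05) or DAC and DEX replicates 3 (0.108), or with the length and GC offset (0.182) or fry (0.167), in a range of 0.00502 to 0.412. Fibroblast and endothelial markers were at 0.929 (0.0183; adjusted p = 0.254 with an estimated correlation), and did not pass without DEX replicate 1 (0.0801), in a range of 0.00904 to 0.254. Epithelial genes did not pass with all libraries (0.395). Their test pointed up and passed without the 3 libraries (median 0.66, 6.10e-08), DAC and DEX replicates 3 (2.56e-07), DAC replicate 3 (0.0225) or DEX replicate 3 (0.00383), and with the length and GC offset (0.00206), in a range of 6.10e-08 to 0.848. Luminal and hormone receptor genes (0.785) pointed up and passed without the 3 libraries (median 0.54, 0.0108), in a range of 0.0108 to 0.998.

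The library labelled DMSO replicate 3 held glucocorticoid-induced transcripts. It was placed on a scale where the other DMSO libraries lie at 0 and the DEX libraries at 1. Genes were first chosen from DAC+DEX against DAC in a fit of those libraries alone, in which 78 rose and 16 fell. Of these, only genes that passed a filter on level and differed in the same direction between the DMSO and DEX libraries setting the scale were used. The choice of genes was therefore not independent of the scale. The median position of the library labelled DMSO replicate 3 was 0.936 over 54 genes that rose and 0.929 over 11 genes that fell. A swap of labels with a DEX library is argued against, since the lowest DEX library lay at 0.898 for the genes that rose and 0.808 for those that fell. A DEX-treated library under the DMSO label stays open, since the DEX libraries spanned 0.898 to 0.983 and 0.808 to 1.11. A mixture of DMSO and DEX RNA also stays open, with shares of DEX RNA of 0.79 and 0.978 on the linear scale that differ by -0.187 ± 0.121, and glucocorticoid exposure of a DMSO culture was not tested.

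DAC replicate 3 and DEX replicate 3 had fewer reads of long genes than the other libraries of their groups. The gap to the nearest library of the group was 1.17 in DAC and 0.877 in DEX, which is the pattern itself and decides nothing about the treatments. Lower depth is argued against: DMSO replicate 2 thinned to the total of DEX replicate 3 measured 0.544 against 0.543 unthinned. Once a smooth on length and GC content was removed, deviations of the pair of libraries from their groups still correlated at 0.615 across genes (0.675 before), so the trend in length and GC is not the whole of what they share. What else they share, such as RNA quality or a preparation batch, is not given in the labels and was not tested.

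For DAC+DEX against DAC, 11 genes were higher and 1 lower, led by KRT6A. Loss of long genes in DAC replicate 3 is argued against, since all 12 were still called without it and DEX replicate 3. Without DAC replicate 3 alone 9 were called, and TGM4, MUCL3 and C5AR2 went from log2 2.22, 3.66 and 3.15 to 2.29, 3.49 and 3.11 (adjusted p = 0.0602, 0.151 and 0.121), with 1 library fewer. Over all alternatives their ranges were 5.02e-07 to 0.181, 1.59e-07 to 0.276 and 2.44e-12 to 0.243. With the replicate block, 11 were called without them, and MUCL3 was at log2 3.63 (0.0774) against 3.70 (0.0512) with the block and all libraries. Epidermal cells in the cultures are argued against: KRT5 and KRT14, abundant keratins of basal epidermis, were at 0.886 and 0.923 CPM with DAC+DEX, together 3.21% of KRT6A. Reads shared between copies are argued against as well, with KRT6B at 0.135% of KRT6A and no read of KRT6C. A joint effect of the compounds on these genes may be a candidate explanation. It was not tested on its own, since the genes were chosen for a difference that is itself a part of the interaction. Adjusted over all genes, the interaction passed for 0 of 12 with all libraries and for 0 without the 3 libraries that stood apart. Without these, KRT6A and DCN were also called with DEX alone (log2 4.39 and 4.32; adjusted p = 0.00864 and 0.0306, in ranges of 1.01e-06 to 0.401 and 1.32e-06 to 0.401).

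Splits of the libraries were counted for each result. Each pair of groups allows 10 splits, too few for a share under 0.05, since the real split alone makes 0.1. The real and the highest other number of genes were 5343 and 0 for DAC against DMSO, 0 and 0 for DEX against DMSO, 3919 and 0 for DAC+DEX against DMSO, 12 and 0 for DAC+DEX against DAC, and 7428 and 0 for DAC+DEX against DEX. For DAC+DEX against DAC, the other 3 splits that part all 3 same-numbered pairs and the 6 that part 1 pair each called 0 genes. Relabelling treats the libraries as independent, so where replicates share a culture it does not speak to chance between cultures. In 100 relabellings of all libraries, a chance labelling of these libraries was excluded for the average DAC effect (8349 genes, highest other 1, reached by 1 of 100). For the average DEX effect (93 genes, reached by 3 of 100) such relabellings decide nothing, since they put the DAC effect into the residual spread, and 97 called 0 genes. The other 2 called 2155 and 1687 genes, for a reason that was not tested. Their DEX arms held 5 and 2 libraries with DAC, and the 3 other relabellings with 5 called 0. With DEX labels shuffled within DAC status, a test added after these results, a chance labelling of these libraries was excluded for the average DEX effect (93 genes, highest other 2). That number was reached by 1 of 100 relabellings drawn from 200, the real one. Chance was not excluded for the number of list tests passed (53, reached by 21 of 100, highest other 74). For the interaction, a real count of 0 is reached by all 100 relabellings (highest other 12), which says nothing about chance.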

How the results depend on the processing

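The alternatives that left out several libraries, the length and GC offset, the sample weights, the replicate block combined with these and the weighted choice of genes were chosen after the data were seen. The cause of the changes below was not tested. Of the named genes, 206 values were called. With single libraries left out, named genes gave the same call and direction 4013 times, lost a call 147 times and gained one 31 times, and with the other alternatives fixed before the data were examined 2626, 52 and 60 times. For list tests these numbers were 1394, 29 and 16, and 412, 60 and 8. With the alternatives chosen after, they were 1360, 19 and 107 for named genes and 445, 17 and 17 for list tests. Values of named genes turned sign by more than their standard error, without a call, 43 times with these and 8 times with single libraries left out. In data simulated at this depth and spread, 0 to 8.96% of genes changed 2-fold were recovered. Few genes were changed in each simulation, so its adjusted threshold was stricter than in contrasts that called many genes. The share recovered therefore does not carry over to the comparisons of DAC-treated groups with DMSO or DEX. Depth was not varied in the simulation, and it limits genes near 3 counts per library.

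Counts that moved over 1.5 times are given as higher and lower genes, with the value from all libraries in the report. At an adjusted p under 0.01, they were 2311 and 704 for DAC against DMSO, 1853 and 274 for DAC+DEX against DMSO, 6 higher for DAC+DEX against DAC, 2513 and 1531 for DAC+DEX against DEX, and 2 shared by the average effects. With library totals alone, DAC against DMSO had 759 lower, DEX against DMSO 3 and 25, DAC+DEX against DMSO 442 lower, DAC+DEX against DAC 2 lower, and DAC+DEX against DEX 1616 lower. DESeq2 gave 210 and 291 for DEX against DMSO, 1477 lower for DAC+DEX against DMSO, 146 and 58 for DAC+DEX against DAC, and 57 and 26 for the interaction. limma-voom gave 51 and 10 for DAC+DEX against DAC. Without a filter, DEX against DMSO had 1021 and 805, DAC+DEX against DAC 368 and 161, and the interaction 1151 and 1110. With only the groups compared, DAC+DEX against DMSO had 2566 lower and DAC+DEX against DAC 127 and 31. With an estimated correlation, 7 list tests passed.

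With the replicate number as a block, DEX against DMSO had 7 and 16, DAC+DEX against DAC 24 and 2, and 122 genes were shared by the average effects. For DAC+DEX against DAC, whose libraries deviated together by number, the block ended the calls of the DNA methylation list, the leukocyte list and MUCL3 and changed no other call of a list or named gene there. In that comparison, the block gave 65 and 15 in the 6 libraries alone, where ENSG00000248187 lost its call, 22 and 5 without DAC replicate 3 and DEX replicate 3, and 90 and 18 with the length and GC offset. Over all groups, same-numbered libraries correlated at -0.333 to 0.674, and not every library correlated best with its own number.

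Without DAC replicate 3 and DEX replicate 3, DAC against DMSO had 3140 lower, DEX against DMSO 1 lower, DAC+DEX against DMSO 4611 and 3129, DAC+DEX against DAC 52 and 9, and the overlap 112. Without these and DMSO replicate 3, the values were 2790 lower, 197 and 314, 2949 lower, 240 and 75, 1 higher for the interaction, and 519 shared, and the DEX effect differed by -0.491 with DAC. With the length and GC offset, DEX against DMSO had 23 and 68, DAC+DEX against DMSO 1834 lower, DAC+DEX against DAC 50 and 7, and the overlap was 176. With sample weights, the counts were 5482 and 4183 for DAC against DMSO, 4736 and 4688 for DEX against DMSO, 5514 and 3854 for DAC+DEX against DMSO, 1120 and 854 for DAC+DEX against DAC, 7948 and 5625 for DAC+DEX against DEX, and 4270 and 3726 for the interaction. These weights were 0.139 for DAC replicate 3, 0.12 for DEX replicate 3 and 8.30 for DEX replicate 2. They were 0.364, 2.32 and 1.12 for DMSO replicates 1, 2 and 3 and 0.455 for DEX replicate 1. The weights therefore lowered DMSO replicate 1, which is kept in the fits without the 3 libraries, more than DMSO replicate 3.

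Directions turned for few results. Without the 3 libraries that stood apart, the interaction list of glucocorticoid-induced genes passed in the other direction (0.0184), and TSC22D3 (log2 0.59, adjusted p = 0.0386) and PER1 (0.95, 0.00284) were higher with DAC than with DMSO. TOP2A for DEX against DMSO was at -0.25 with sample weights. With single libraries left out, PER1 for DAC against DMSO ranged from -0.68 to 0.89 and the epithelial list for DAC+DEX against DAC had an adjusted p from 0.0434 to 1.00.

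With single libraries left out, ranges of higher and of lower genes were 2875 to 4603 and 1127 to 2935 for DAC against DMSO, 0 to 1209 and 0 to 500 for DEX against DMSO, 2146 to 3865 and 370 to 1908 for DAC+DEX against DMSO, 3 to 74 and 0 to 18 for DAC+DEX against DAC, 3168 to 4942 and 1855 to 3808 for DAC+DEX against DEX, and 0 to 580 and 0 to 1094 for the interaction. The difference in the DEX effect ranged from -0.709 to 3.72, that in the DAC effect from 0.0517 to 0.439, the overlap from 2 to 207, the genes silent in DMSO and expressed with DAC from 290 to 352, and the list tests passed from 49 to 58. The number of genes silent in DMSO and expressed with DAC can only stay or rise when a library is left out. With genes chosen by an average weighted for group size, the difference in the DEX effect was -0.439 without the 3 libraries that stood apart, -0.621 without DMSO replicate 3, 0.0466 and 0.464 without DMSO replicates 1 and 2, 0.506 without DEX replicate 2 and 3.72 without DAC+DEX replicate 2. These medians covered 744, 311, 61, 30, 17 and 2 genes in this order. The difference in the DAC effect was 0.352 without DEX replicate 1.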

Other observations

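Genes switched on by DAC were often X-linked. Of 209 coding genes silent in every DMSO library and expressed in every DAC library, 35 lay on the X chromosome (16.8%), against 271 of 4702 other coding genes silent in DMSO (5.76%; odds ratio 3.29, 95% interval 2.17 to 4.86, exact Fisher p = 4.09e-08). This test was chosen after the result was seen. Without cancer-testis families, 16 of 184 gained genes (8.70%) and 202 of 4625 others (4.37%) were X-linked (odds ratio 2.09, 95% interval 1.14 to 3.57, exact Fisher p = 0.0104). Neighbouring genes are not independent, and a larger X-linked share beyond these families remains a hypothesis. With DAC+DEX, 210 genes silent in DMSO were expressed and none went the other way, and with DEX 0 were gained and 1 was lost. Without the 3 libraries that stood apart, 37 of 274 coding genes gained with DAC were X-linked, DAC+DEX gained 274 genes in all, and DEX gained 6 and lost 4. These numbers of gained and lost genes can only stay or rise when libraries are left out.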
